A study of Mus musculus with 9 samples.

How the data were processed

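RNA sequencing measured transcript levels in mouse embryonic fibroblasts that lack β-actin (Actb knockout, BALB/c strain, from embryos of day 10.5). The cells were transfected for 6 h with 10 µg/ml poly(dA:dT), a synthetic double-stranded DNA, or 10 µg/ml poly(I:C), a synthetic double-stranded RNA. A cationic lipid reagent in Opti-MEM medium was the carrier, and mock cells received the carrier alone. Each of the 3 groups held 3 libraries, 9 in total. Per the labels' protocols, total RNA was extracted with an RNeasy kit and libraries were made with a TruSeq RNA kit that does not mark the strand. Wild-type cells were not analysed here.

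The deposited values were raw read counts per Ensembl gene, 1 file per library, each holding 46603 gene identifiers and no summary lines for unassigned reads. Per the submitters' processing notes, TopHat2 2.1.0, HTSeq and DESeq2 were used with the GRCm38.p4 genome build. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The counts were used as deposited by the authors. Symbols, gene types and positions came from the GENCODE M21 annotation of GRCm38, matched on the Ensembl identifier. It held 46091 of the identifiers, and the other 512 carried 0.0588% of the counts.

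Counts assigned to genes summed to between 16082772 and 29219797 per library. At these depths 3 counts, the limit that a count of 0 allows, correspond to 0.107 to 0.18 CPM, the counts relative to library size that the cpm function of edgeR gives. Counting intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. The 3 replicates of a group were compared by a chi-square test on genes with at least 20 counts. The statistic per degree of freedom lay between 1.64 and 2.1 in the 9 pairs, so no pair agreed within sampling noise, and every library was counted once. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels name no batch.

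Genes were tested with edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood test in robust mode, two-sided. TMM scaling was used, and genes were filtered with filterByExpr by group, which left 14176 genes. All 9 libraries entered 1 fit with a mean per group, which gave 6 residual degrees of freedom before moderation. The 3 contrasts were poly(dA:dT) against mock, poly(I:C) against mock, and poly(I:C) against poly(dA:dT). Adjusted p-values are by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and genes past it are called. CPM values were computed with the TMM-scaled library sizes and are given as mean ± SD of 3 libraries. Log2 fold changes are fitted values and used a prior count of 0.125. Their standard error (SE) is the absolute log2 fold change divided by the square root of the test's F statistic. Where the lower group had 0 counts, the fold is a lower bound set by 3 counts over the group. Where it had 1 to 3 counts, the fold is a ratio with its 95% counting interval. Where both groups had over 3 counts, a 95% interval comes from the log2 fold change and its SE.

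Before the data were examined, 26 gene lists were fixed: type I and III interferons, interferon-stimulated effectors, interferon-inducible GTPases, nucleic acid sensors, interferon receptors with IRF and STAT factors, cytokines and chemokines, NF-kB targets, MHC class I antigen presentation, cell death, integrated stress and unfolded protein response, p53 targets, immediate early genes, S phase, G2 and M phase, actin and contractile genes, extracellular matrix, cholesterol synthesis, glycolysis and hypoxia, nuclear genes of oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins, and markers of macrophages, endothelium, epithelium, neural cells and skeletal muscle. All 578 listed symbols were matched, 1 through an older symbol. The 25 lists with at least 5 tested members were tested with camera in limma 3.58.1, which compares a list with all other genes. It does not match these genes for abundance. Its inter-gene correlation was preset at 0.01, and p-values were adjusted within each comparison. The test was repeated with an estimated correlation and with fry, which asks whether a list's genes move on balance in the same direction and makes no comparison with other genes. Member counts were also taken with p-values adjusted over the list alone.

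Genes are named by a rule fixed before the data were examined. It takes Actb, the 10 genes with the largest rise and the 10 with the largest fall in each comparison, up to 4 changed members of each list, and 25 key genes. The 10 per direction had to be called, reach a mean of 1 CPM, carry a symbol other than a predicted gene's, and have CPM values that did not overlap between the groups. Members named outside this rule are marked as named after their values were seen. Some genes that the rule takes are not reported here.

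Alternatives were fixed in advance: DESeq2 size factors, upper-quartile factors or total counts as the scaling, no filter, a filter of at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, fits of only the groups compared, the replicate number as a block, and each library left out in turn. The overlap between the treatments was set beside independent lists and beside 20 simulated draws of unchanged groups. In each draw all 9 libraries were simulated from the mock means, and both comparisons shared the simulated mock libraries. The edgeR step was tested on simulated counts for the 14176 genes, with 200 genes changed, 50 at each fold. Equal numbers were raised and lowered. The real comparisons called 7490, 10787 and 8981 genes, with changes of at least 2-fold mostly upward. The shares below therefore do not test the scaling under changes so many and so one-sided. For poly(dA:dT) against mock it recovered 66% of genes changed 1.2-fold, 86% of those changed 2-fold and 98% of those changed 4-fold, with 11 false calls among 177. For poly(I:C) against mock the shares were 66%, 82% and 92%, with 3 false calls among 165. For poly(I:C) against poly(dA:dT) they were 60%, 80% and 94%, with 4 false calls among 157.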

Results

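The transcriptome of β-actin knockout mouse embryonic fibroblasts was profiled by RNA sequencing 6 h after transfection with poly(dA:dT), with poly(I:C) or with the reagent alone (mock), with 3 libraries per group. Poly(dA:dT) mimics viral double-stranded DNA and poly(I:C) mimics viral double-stranded RNA, and the series asks which genes change after these mimics in cells without β-actin. Assigned counts per library ranged from 19826550 to 29219797 in the mock group, from 20738109 to 23185293 after poly(dA:dT), and from 16082772 to 22382837 after poly(I:C). Genes with at least 1 count numbered 18468 ± 356 in mock, 18997 ± 146 after poly(dA:dT) and 20140 ± 439 after poly(I:C) (SD, n = 3). The first principal component held 80% of the variance and placed the poly(dA:dT) libraries between those of mock and poly(I:C).

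Actb (ENSMUSG00000029580, chromosome 5, 142903115 to 142906754, minus strand, GRCm38), the knocked-out gene, had 924, 772 and 658 counts in mock replicates 1 to 3, 657, 680 and 716 after poly(dA:dT), and 649, 736 and 565 after poly(I:C). This was 33.3 ± 1.29, 30.6 ± 1.29 and 32.4 ± 1.34 CPM (SD, n = 3). γ-Actin, encoded by Actg1 (ENSMUSG00000062825, chromosome 11, 120345690 to 120348542), stood at 3438 ± 29.7 CPM in mock. Smooth muscle actin, encoded by Acta2, stood at 3154 ± 31 CPM. The extent of the deletion is not given in the sources used here, and Actb can share reads with other actin genes and pseudogenes, so the remaining counts cannot be assigned to an intact transcript. In the edgeR quasi-likelihood test Actb was not called in any of the 3 comparisons (adjusted p = 0.0613, 0.52 and 0.223). It was called lower after poly(dA:dT) than in mock with DESeq2 size factors (log2 fold change -0.14, adjusted p = 0.029) and without mock replicate 2 (-0.15, adjusted p = 0.0453).

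Poly(dA:dT) was compared with mock to find the response to the transfected DNA mimic. The transcript of interferon β, the main early antiviral cytokine of fibroblasts, rose from 1 count over the 3 mock libraries to 4.87 ± 0.789 CPM (Ifnb1, ENSMUSG00000048806, chromosome 4, 88522025 to 88522774). This was a ratio of 343, with a 95% counting interval of 61.2 to 13600. Genes that interferon induces rose with it: Ifit1, which binds foreign RNA caps, went from 1.29 ± 0.0611 to 124 ± 0.793 CPM, and Isg15, a ubiquitin-like modifier, from 1.94 ± 0.369 to 30.1 ± 1.92 CPM. Transcripts of p53 target genes and immediate early genes rose as well, while those of G2 and M phase, oxidative phosphorylation, glycolysis and actin genes fell by small amounts. Of 14176 genes tested, 3769 were called higher and 3721 lower, and changes of at least 2-fold were nearly all increases, 544 up and 9 down.

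Among 47 tested interferon-stimulated effectors, 38 rose, 0 fell and 9 were not called after poly(dA:dT), and 28 rose at least 2-fold (camera, adjusted p = 2.27e-16). Adjusted over the list alone, 40 rose. Beside Ifit1, the antiviral GTPase gene Mx2 rose from 0.28 ± 0.0148 to 25.3 ± 0.61 CPM, the helicase gene Ddx60 by 6.18 ± 0.22 (SE) on the log2 scale, and Oasl1 by 6.42 ± 0.22. Of the 15 interferon-inducible GTPases, which act on vacuoles that hold pathogens, 12 rose and 3 were not called (adjusted p = 9.98e-09), and all 15 rose when adjusted over the list alone. Gbp5 rose from 0.216 ± 0.0976 to 18.2 ± 0.498 CPM. Tgtp1 had 1 count in mock and rose by a ratio of 24.3 (interval 3.94 to 1000), but Tgtp1 and Tgtp2 are near-identical copies and their separate values are uncertain. Among 21 nucleic acid sensors and adaptors, 14 rose, 1 fell and 6 were not called, with equal counts adjusted over the list alone (adjusted p = 6.76e-05). None fell without mock replicate 1 or 3, without poly(dA:dT) replicate 2 or 3, with DESeq2, with upper-quartile factors or total counts, with either other filter, or in a fit of only the groups compared. The RNA sensor genes Ifih1 and Ddx58 rose 6.43-fold and 2.18-fold, and the DNA sensor gene Cgas rose 1.22-fold from 53.3 ± 2.06 CPM. Of 18 interferon receptor, IRF and STAT genes, 10 rose, 1 fell and 7 were not called (adjusted p = 0.000573), and 11 rose adjusted over the list alone. Irf7, the factor that amplifies interferon transcription, rose from 2.96 ± 0.606 to 11.9 ± 0.312 CPM, and Irf1 rose 2.49-fold.

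Secreted signals rose with the interferon genes after poly(dA:dT). Of 23 cytokines and chemokines, 18 rose, 1 fell and 4 were not called (camera, adjusted p = 2.93e-07), and 19 rose adjusted over the list alone. Ccl5 rose from 2.09 ± 0.247 to 58.9 ± 1.35 CPM, Cxcl10 from 9.6 ± 0.584 to 132 ± 2.43 CPM, and Il6 from 0.518 ± 0.177 to 6.25 ± 1.64 CPM. The member that fell was Cxcl12, a constitutive stromal chemokine (named after its values were seen), with a log2 fold change of -0.54 ± 0.02 (SE). Of 25 NF-kB feedback and target genes, 22 rose, 1 fell and 2 were not called, with equal counts adjusted over the list alone (adjusted p = 1.89e-09). Icam1, a leukocyte adhesion molecule, rose 6.65-fold, and Tnfaip3, an inhibitor of NF-kB signalling, rose 2.97-fold. Among the interferon genes themselves only Ifnb1 and Ifna4 passed the filter. Ifna4 had 0 counts in mock and was at least 4.93-fold higher after poly(dA:dT).

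The MHC class I list did not stand apart from other genes after poly(dA:dT) (camera, adjusted p = 0.822). Of its 19 members 5 rose, 5 fell and 9 were not called, also adjusted over the list alone, and the median log2 fold change was -0.00358 where the mean was 0.12 and the direction of the test was upward. H2-Q7 rose 3.28-fold and Tap1, a peptide transporter, 1.71-fold, and near-identical H2 genes can exchange reads. H2-K1 stood at 47.9 ± 0.998 CPM in mock and 50 ± 1.93 CPM after poly(dA:dT). The number that rose was 3 without mock replicate 2 or poly(dA:dT) replicate 1, with DESeq2 or its size factors and without a filter. It was 10 with total counts as the scaling. The median became positive with total counts, at 0.0705, and with upper-quartile factors, at 0.0178.

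p53 target genes rose after poly(dA:dT), with 16 of 20 higher, 2 lower and 2 not called, also adjusted over the list alone (camera, adjusted p = 1.23e-07). Without poly(dA:dT) replicate 1, or with total counts, 1 was lower. Mdm2, the ubiquitin ligase that restrains p53, rose from 98.7 ± 3.1 to 244 ± 4.91 CPM. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose from 85 ± 1.66 to 186 ± 2.19 CPM, and Btg2 from 11.6 ± 0.836 to 52.2 ± 3.56 CPM. Of 23 immediate early genes 19 rose and 4 were not called, with equal counts adjusted over the list alone (adjusted p = 1.67e-11). Egr1 rose 3.5-fold, and Fos rose from 1.8 ± 0.209 to 8.77 ± 0.185 CPM. The integrated stress and unfolded protein response list split, with 12 higher, 10 lower and 2 not called, and 13 higher adjusted over the list alone (adjusted p = 0.107). Atf3, a stress-induced transcription factor, rose 6.27-fold, and Chac1 and Trib3, both induced in the integrated stress response, rose 3.46-fold and 2.66-fold. Of 26 cell death genes 10 rose, 9 fell and 7 were not called, also adjusted over the list alone (adjusted p = 0.577), and 5 fell without poly(dA:dT) replicate 3, 4 fell with total counts, and 6 rose with DESeq2. The BH3-only genes Pmaip1 and Bbc3 rose 3.69-fold and 2.01-fold.

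Several abundant gene groups fell after poly(dA:dT), each by less than 2-fold. Median log2 fold changes of the oxidative phosphorylation, G2 and M phase, actin, glycolysis, matrix and ribosomal lists lay close together, at -0.19 to -0.21. With total counts they were -0.12 to -0.14. Whether these lists fell more than other abundant genes was not tested. All 27 nuclear genes of oxidative phosphorylation fell, also adjusted over the list alone, with a median log2 fold change of -0.21 (camera, adjusted p = 6.07e-09). Of 25 genes of G2 and M phase 21 fell and 4 were not called (adjusted p = 6.74e-09), and 22 fell adjusted over the list alone, while total counts gave 1 that rose. Cenpf, a kinetochore protein, showed a log2 fold change of -0.42 ± 0.03 (SE), and Ccnb1, cyclin B1, one of -0.29 ± 0.02. Of 22 actin and contractile genes 15 fell, 2 rose and 5 were not called (adjusted p = 1.94e-05), and 16 fell adjusted over the list alone, while 4 rose with total counts and 1 with DESeq2. Actg1 fell to 2873 ± 19.6 CPM and Acta2 to 2560 ± 14.1 CPM. Of 22 glycolysis and hypoxia genes 14 fell, 2 rose and 6 were not called, also adjusted over the list alone (adjusted p = 0.000237). Pgam1 fell, while Vegfa and Hk2 rose 1.39-fold and 1.24-fold.

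In 3 further lists that fell after poly(dA:dT), the camera call was lost once the correlation was estimated. Of 27 extracellular matrix genes 19 fell, 4 rose and 4 were not called, and 5 rose adjusted over the list alone (adjusted p = 0.000174, and adjusted p = 0.0641 with an estimated correlation), while DESeq2 gave 2 that rose. Col3a1 fell from 227 ± 0.48 to 169 ± 2.34 CPM, and Sparc from 1158 ± 3.06 to 907 ± 1.69 CPM. Of 28 ribosomal protein genes 26 fell and 2 rose, also adjusted over the list alone (adjusted p = 4.73e-10, and adjusted p = 0.0746 with an estimated correlation). Only 1 rose without mock replicate 3, without poly(dA:dT) replicate 1 or 3, with DESeq2 or its size factors, or without a filter. Rpl11 had a log2 fold change of -0.34 ± 0.02 (SE). Of 10 mitochondrially encoded transcripts 8 fell and 2 were not called, also adjusted over the list alone (adjusted p = 1.88e-05, and adjusted p = 0.0549 with an estimated correlation). mt-Nd1 fell from 912 ± 21.3 to 662 ± 4.22 CPM, and the share of counts on mitochondrial genes was 0.32% ± 0.0029 in mock and 0.261% ± 0.0019 after poly(dA:dT) (SD, n = 3).

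S phase genes (7 rose, 6 fell and 12 were not called, camera adjusted p = 0.577) and cholesterol synthesis genes (4 rose, 8 fell and 12 were not called, adjusted p = 0.225) did not stand apart after poly(dA:dT). Adjusted over the list alone, 7 S phase genes fell and the other counts were equal. The replication genes Pole and Mcm10 rose 1.4-fold and 1.38-fold. With upper-quartile factors 11 S phase genes rose, with total counts 14 rose and 2 fell, and 7 cholesterol genes rose and 4 fell, with a median of 0.0282 in place of -0.0459. Just 2 cholesterol genes rose without mock replicate 2, without poly(dA:dT) replicate 1, with DESeq2 or its size factors, or without a filter. None of the marker lists of other cell types was called. The counts were 0 of 6 macrophage markers higher and 1 lower (adjusted p = 0.577), 3 of 6 endothelial markers higher (adjusted p = 0.316), 0 of 5 epithelial markers changed (adjusted p = 0.517), 2 of 6 neural markers lower (adjusted p = 0.316) and 0 of 5 muscle markers changed (adjusted p = 0.939). These counts were equal when adjusted over the list alone. The macrophage list had a median log2 fold change of -0.16, a mean of 0.03 and a downward test direction, and the muscle list had 0.03, 0.12 and a downward direction. The macrophage marker was not lower without poly(dA:dT) replicate 1 or with DESeq2, 1 epithelial marker was lower without poly(dA:dT) replicate 2, 1 neural marker was lower with total counts, and 0 endothelial markers were higher under the filter of 50 counts. The endothelial genes stayed low, with Pecam1 at 1.29 ± 0.146 CPM and Kdr at 1.22 ± 0.277 CPM.

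Among genes that the naming rule admits, the largest falls after poly(dA:dT) were in genes of low expression. Npr3, a natriuretic peptide clearance receptor, fell from 5.7 ± 0.464 to 3.04 ± 0.293 CPM, and Dpt, a matrix protein, from 1.8 ± 0.295 to 0.889 ± 0.173 CPM. Of the 14176 genes, 57.3% had CPM values that did not overlap between poly(dA:dT) and mock, where chance gives 10%. The balance of calls depended on the scaling: with total counts 5004 genes were called higher and 2389 lower, a share of 67.7% higher against 50.3% with TMM. A filter of at least 50 counts in 3 libraries left 299 genes changed at least 2-fold among the 11717 it tested.

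**Figure D1:**
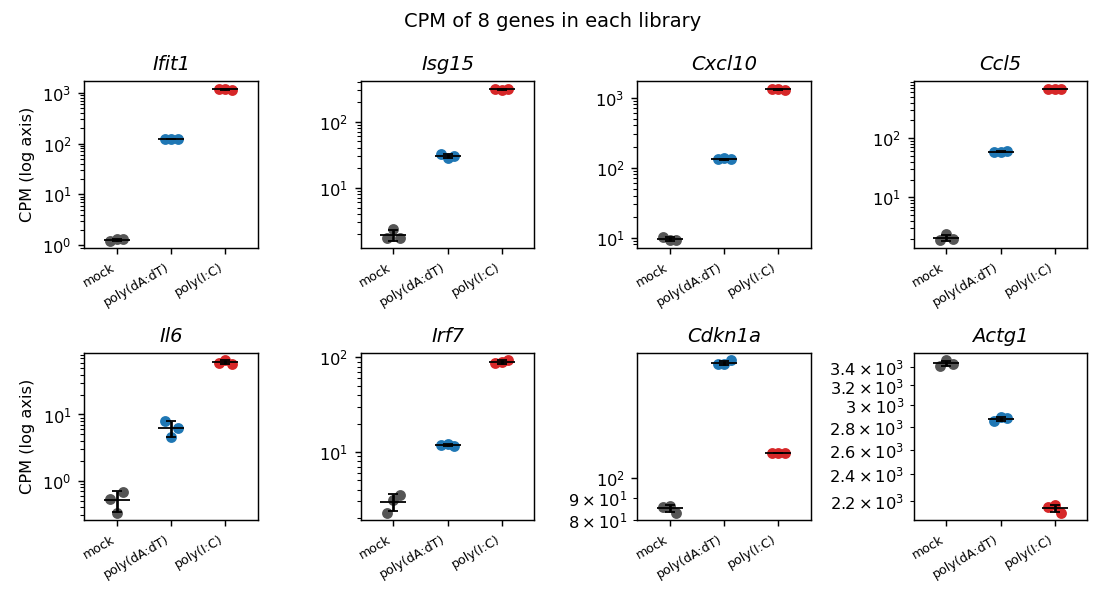
Expression of 8 genes in each of the 9 libraries, in CPM on logarithmic axes; points are libraries, horizontal lines are group means and bars are the SD of 3 libraries. Ifit1, Isg15, Cxcl10, Ccl5, Il6 and Irf7 stood lowest in mock and highest after poly(I:C), Cdkn1a stood highest after poly(dA:dT) (186 CPM), and Actg1 fell from 3438 CPM in mock to 2150 CPM after poly(I:C).

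Poly(I:C) was compared with mock to find the response to the transfected RNA mimic. Ifnb1 rose from 1 count in mock to 88.2 ± 5.6 CPM, a ratio of 6290 with a counting interval of 1130 to 249000. Ifit1 reached 1176 ± 25.2 CPM (914-fold), Cxcl10, a chemokine for T cells, reached 1312 ± 28.8 CPM (137-fold), and Isg15 reached 308 ± 5.73 CPM (159-fold). All 47 interferon-stimulated effectors and all 23 immediate early genes rose, while genes of cholesterol synthesis, cell division and oxidative phosphorylation fell. Of 14176 genes, 5647 were called higher and 5140 lower, and 1858 rose and 148 fell at least 2-fold.

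All 47 effectors rose after poly(I:C) also when adjusted over the list alone, 45 of them at least 2-fold (camera, adjusted p = 3.36e-19). Oasl1, of the oligoadenylate synthetase family, rose from 0.101 ± 0.0918 to 222 ± 2.68 CPM, and Mx2 from 0.28 ± 0.0148 to 332 ± 4.91 CPM. All 15 inducible GTPases rose, each at least 2-fold and also adjusted over the list alone (adjusted p = 1.46e-08), and Gbp5 reached 266 ± 0.847 CPM. Of 21 sensors and adaptors 16 rose and 5 were not called, also adjusted over the list alone (adjusted p = 5.4e-05), and 1 fell without poly(I:C) replicate 1, with DESeq2 size factors, without a filter or in a fit of only the groups compared. Ifih1 rose 52.7-fold, Ddx58 11.6-fold and Cgas 2.11-fold. Zbp1, a sensor of Z-form nucleic acids, had 3 counts in mock and rose by a ratio of 158 (interval 53.8 to 772). Of 18 receptor, IRF and STAT genes 15 rose, 2 fell and 1 was not called, also adjusted over the list alone (adjusted p = 1.73e-05). The number that fell was 1 without mock replicate 1, without poly(I:C) replicate 2 or 3, with upper-quartile factors or total counts, or under the filter of 50 counts. Irf7 reached 89.2 ± 3.47 CPM (30.1-fold), and Stat2, a part of the interferon-induced transcription complex, rose 12.8-fold.

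Of 23 cytokines and chemokines 21 rose, 1 fell and 1 was not called after poly(I:C), also adjusted over the list alone (camera, adjusted p = 7.27e-09). Ccl5 rose 327-fold to 683 ± 5.48 CPM, Il6 118-fold to 61.3 ± 3.96 CPM, and Cxcl11 394-fold. Tnf had 1 count in mock and reached 28.9 ± 0.873 CPM, while Cxcl12 again was the member that fell, with a log2 fold change of -1.15 ± 0.02 (SE). Acod1, which makes itaconate, had 0 counts in mock and was at least 152-fold higher. Of 25 NF-kB genes 24 rose and 1 was not called, also adjusted over the list alone (adjusted p = 1.55e-10), with Icam1 at 90.4-fold and Tnfaip3 at 14.5-fold. MHC class I genes rose, with 15 higher, 3 lower and 1 not called, also adjusted over the list alone (adjusted p = 0.000115), and 1 lower with total counts or under the filter of 50 counts. H2-K1 rose 2.28-fold and Tap1 4.93-fold. Ifna4 was at least 89.6-fold higher than in mock, and among the interferon genes below the filter Ifna1 had 6, 8 and 9 counts and Ifna16 had 6, 5 and 6 counts in the poly(I:C) libraries, both with 0 counts in mock. Ifna14 and Ifne had 2 and 4 counts over the mock libraries and 0 and 2 counts after poly(I:C). Ifnl2 and Ifnl3, of the interferon λ family, had at most 1 count in any library.

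Immediate early genes rose in all 23 cases after poly(I:C), also adjusted over the list alone (camera, adjusted p = 3.46e-10), with Egr1 at 12.8-fold and Egr2 at 16.2-fold. The integrated stress and unfolded protein response list held 12 genes that rose and 12 that fell, also adjusted over the list alone (adjusted p = 0.91). Its median log2 fold change was -0.11 and its mean 0.34, camera gave a downward and fry an upward direction, and the median was 0.00437 with total counts. Atf3 rose 23.5-fold and Ppp1r15a, which directs removal of the phosphate from eIF2α, 9.61-fold. Of 20 p53 targets 10 rose, 8 fell and 2 were not called, also adjusted over the list alone (adjusted p = 0.608). Pmaip1 rose 8.05-fold, and Trp53inp1, a p53-induced nuclear protein, fell from 16.3 ± 1.46 to 9.37 ± 0.302 CPM. Of 26 cell death genes 14 rose, 10 fell and 2 were not called (adjusted p = 0.329), and 15 rose adjusted over the list alone. Casp4, an inflammatory caspase, rose 4.91-fold.

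The 24 cholesterol synthesis genes fell in 20 cases, rose in 2 and were not called in 2 after poly(I:C), also adjusted over the list alone (camera, adjusted p = 2.26e-05), and DESeq2 gave 1 that rose. Sqle, which encodes squalene epoxidase, fell from 219 ± 2.16 to 111 ± 0.847 CPM. All 27 nuclear genes of oxidative phosphorylation fell, also adjusted over the list alone (adjusted p = 7.36e-09), with a median log2 fold change of -0.46. Of 25 genes of G2 and M phase 22 fell, 1 rose and 2 were not called, also adjusted over the list alone (adjusted p = 2.16e-07), and 2 rose with upper-quartile factors or total counts or under the filter of 50 counts. Ccnb1 fell from 283 ± 3.42 to 165 ± 4.22 CPM. S phase genes split into 16 higher, 6 lower and 3 not called, also adjusted over the list alone (adjusted p = 0.168), and Pole rose from 160 ± 0.162 to 321 ± 3.75 CPM. Of 22 actin and contractile genes 17 fell, 2 rose and 3 were not called, also adjusted over the list alone (adjusted p = 0.000101), and 4 rose with total counts. Actg1 fell to 2150 ± 26 CPM and Myl9, a myosin light chain, from 452 ± 4.83 to 266 ± 2.18 CPM. Of 22 glycolysis and hypoxia genes 15 fell, 4 rose and 3 were not called, also adjusted over the list alone (camera, adjusted p = 0.00184). Hk2, the first enzyme of glycolysis, had a log2 fold change of 0.97 ± 0.05 (SE). Medians of the cholesterol, oxidative phosphorylation, G2 and M phase, actin and glycolysis lists lay between -0.39 and -0.49. Whether these lists fell more than other abundant genes was not tested.

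Extracellular matrix genes fell in 19 cases, rose in 4 and were not called in 4 after poly(I:C), also adjusted over the list alone (camera, adjusted p = 0.000672, and adjusted p = 0.0893 with an estimated correlation). Col3a1 fell to 102 ± 2.73 CPM and Sparc to 558 ± 1.09 CPM. Ribosomal protein genes fell in 26 of 28 cases and rose in 2, also adjusted over the list alone (adjusted p = 1.46e-08, and adjusted p = 0.105 with an estimated correlation). Mitochondrially encoded transcripts moved opposite to poly(dA:dT), with 8 of 10 higher, 1 lower and 1 not called, also adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.231 with an estimated correlation). None was lower without mock replicate 3, without poly(I:C) replicate 1, with DESeq2 or total counts, or under the filter of 50 counts. mt-Cytb rose from 392 ± 3.72 to 587 ± 12.2 CPM, and mitochondrial genes held 0.432% ± 0.01 of the counts (SD, n = 3). Reads of mitochondrial genes can be shared with nuclear copies, and 3 of the 13 listed genes lay below the filter. Per library mt-Co2 had 1 to 5 counts, mt-Co3 had 0 to 8 and mt-Nd4l had 0. How completely mitochondrial reads were counted is not known, so the directions in all 3 comparisons hold only for the reads that were counted.

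Marker lists of other cell types were not called after poly(I:C). Of 6 macrophage markers 2 rose and 3 fell (camera, adjusted p = 0.91), of 6 endothelial markers 3 rose and 1 fell (adjusted p = 0.349), of 5 epithelial markers 2 rose and 2 fell (adjusted p = 0.728), of 6 neural markers 3 fell (adjusted p = 0.316), and of 5 muscle markers 1 rose and 2 fell (adjusted p = 0.958). These counts were equal when adjusted over the list alone. With a downward test direction, the median and mean log2 fold change were -0.14 and 0.80 for macrophage, -0.21 and 0.27 for epithelial, and 0.38 and 0.35 for muscle markers. These small counts moved by over 1.5 times in several alternatives: under the filter of 50 counts 0 macrophage, endothelial, epithelial and muscle markers rose, and DESeq2 gave 5 endothelial, 1 epithelial, 2 neural and 2 muscle markers that rose. With a library left out, 1 epithelial marker rose (mock replicate 1 or poly(I:C) replicate 1), 1 neural marker rose (any mock replicate or poly(I:C) replicate 3), 2 muscle markers rose (mock replicate 2 or 3, poly(I:C) replicate 1 or 2), 1 muscle marker fell (poly(I:C) replicate 2) and 0 endothelial markers fell (mock replicate 1). Ptprc, the pan-leukocyte marker, had 0 counts in all 9 libraries, and the macrophage markers that rose, Aif1 and Mpeg1, stood at 0.825 ± 0.176 and 1.3 ± 0.534 CPM. Among genes that the naming rule admits, the largest falls included S100a11, a calcium-binding protein gene, from 520 ± 9.1 to 197 ± 5.61 CPM. They also included Gstm1, a glutathione transferase gene, from 145 ± 5.43 to 58.7 ± 1.47 CPM, and Rab7b from 16.7 ± 0.89 to 5.05 ± 0.432 CPM.

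The 1366 annotated olfactory, vomeronasal and taste receptor genes, of which 97 had any count, summed to 4.14 ± 0.279 CPM in mock, 4.65 ± 0.299 after poly(dA:dT) and 14.2 ± 0.474 after poly(I:C) (SD, n = 3), beside the 1858 genes that rose at least 2-fold after poly(I:C). Of the 14176 genes, 76.8% had CPM values that did not overlap between poly(I:C) and mock, where chance gives 10%. Total counts as the scaling moved the median of all genes from 0.0363 to 0.151 on the log2 scale, with 62.2% of calls higher against 52.4%, so small changes are relative to the scaling. A filter of at least 50 counts in 3 libraries left 1151 genes changed at least 2-fold.

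**Figure D2:**
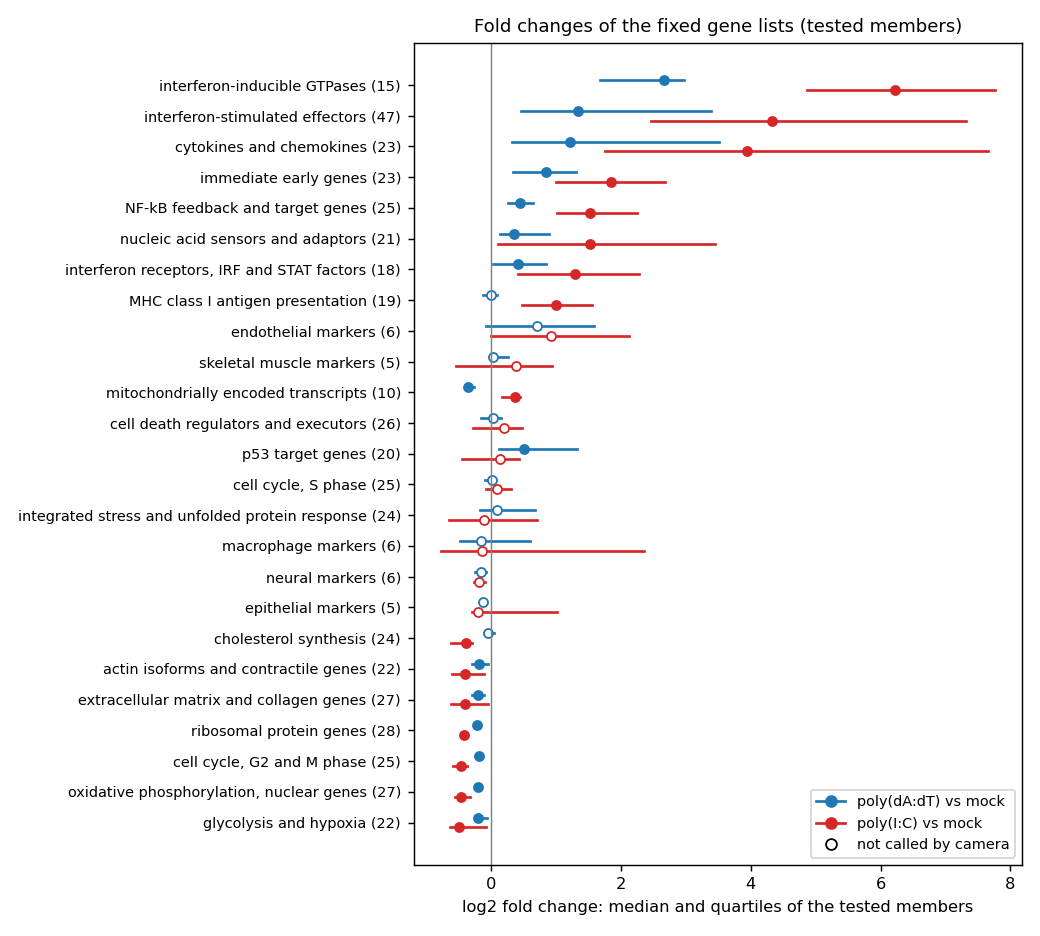
Log2 fold changes of the tested members of 25 gene lists after poly(dA:dT) and after poly(I:C), each against mock; points are medians, lines span the quartiles, numbers in brackets are tested members, and open points are lists that camera did not call. The inducible GTPases, interferon-stimulated effectors and cytokines have the highest medians in both treatments (2.66, 1.34 and 1.22 after poly(dA:dT); 6.23, 4.33 and 3.94 after poly(I:C)), and the median of the p53 target list lies at 0.51 after poly(dA:dT) and at 0.14 after poly(I:C).

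The treatments were compared directly to find where the responses to RNA and DNA mimics differ. Each mimic was given at 10 µg/ml for 6 h only, and their delivery into the cells was not compared here. Every tested interferon-stimulated effector (47), inducible GTPase (15) and NF-kB gene (25) was higher after poly(I:C) than after poly(dA:dT). Ifnb1 was 18.1-fold higher (interval from the SE, 16.5 to 20.1), Ifit1 9.5-fold, Cxcl10 9.9-fold and Il6 9.81-fold. p53 targets went the other way: Cdkn1a, Mdm2 and Trp53inp1 were lower after poly(I:C) than after poly(dA:dT). Of these only Trp53inp1 also stood below mock, while Cdkn1a and Mdm2 stood above it. Cdkn1a was at 83.1 to 86.13 CPM in the mock libraries and at 114.1 CPM in those of poly(I:C). Cholesterol synthesis genes were also lower after poly(I:C) than after poly(dA:dT). Of 14176 genes, 4434 were called higher and 4547 lower after poly(I:C), with 1080 higher and 58 lower at least 2-fold.

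The 47 effectors, 15 GTPases and 25 NF-kB genes were called higher also when adjusted over their lists alone (camera, adjusted p = 7.46e-25, 1.6e-10 and 1.57e-14). Rsad2, the antiviral enzyme viperin, was 14.2-fold and Mx1 19.3-fold higher after poly(I:C). Iigp1 stood at 0.72 ± 0.209 CPM after poly(dA:dT) and 22.3 ± 0.789 CPM after poly(I:C). Of 23 cytokines and chemokines 21 were higher, 1 lower and 1 not called (adjusted p = 2.34e-11), with Tnf 39.9-fold and Cxcl2 22.4-fold higher. Of 21 sensors 13 were higher, 2 lower and 6 not called (adjusted p = 4.97e-06), of 18 receptor, IRF and STAT genes 15 were higher, 1 lower and 2 not called (adjusted p = 4.44e-07), and of 19 MHC class I genes 17 were higher, 1 lower and 1 not called (adjusted p = 9.67e-09). The lower MHC class I gene was not called without poly(dA:dT) replicate 2 or 3, without any 1 of the poly(I:C) replicates, with DESeq2, limma-voom, upper-quartile factors or total counts, or under the filter of 50 counts. The lower receptor, IRF or STAT gene was not called with total counts. Irf7 was 7.48-fold and H2-D1 3.07-fold higher. Of 23 immediate early genes 21 were higher, 1 lower and 1 not called (adjusted p = 1.6e-10). The lower immediate early gene was Fosb, at 5.46 ± 0.807 CPM after poly(dA:dT) and 2.2 ± 0.378 CPM after poly(I:C). Counts of these lists were equal when adjusted over the list alone.

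Of 20 p53 targets 16 were lower after poly(I:C) than after poly(dA:dT), 1 was higher and 3 were not called (camera, adjusted p = 8.87e-07), and 17 were lower adjusted over the list alone. Cdkn1a stood at 186 ± 2.19 CPM after poly(dA:dT) and 114 ± 0.0336 after poly(I:C), Mdm2 at 244 ± 4.91 and 131 ± 3.14, and Ddit4l at 25.4 ± 0.656 and 9.33 ± 0.291. The member that was higher was Pmaip1, 2.18-fold. Wnt9a, a Wnt ligand gene outside the list, stood at 15.4 ± 1.46 CPM after poly(dA:dT) and 5.05 ± 0.748 after poly(I:C). Of 24 stress response genes 7 were higher, 14 lower and 3 not called, also adjusted over the list alone (adjusted p = 0.0346, and adjusted p = 0.196 with an estimated correlation). Its call also ended under the filter of 50 counts (adjusted p = 0.0656). Ddit4 was lower (0.498-fold) and Ppp1r15a 3.85-fold higher. Of 26 cell death genes 14 were higher, 9 lower and 3 not called (adjusted p = 0.286), and 10 were lower adjusted over the list alone.

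Of 24 cholesterol synthesis genes 20 were lower, 1 higher and 3 not called after poly(I:C) compared with poly(dA:dT), also adjusted over the list alone (camera, adjusted p = 4.44e-07). The higher gene was not called without poly(dA:dT) replicate 1, without poly(I:C) replicate 1 or 2, with DESeq2 or without a filter. Sqle stood at 194 ± 3.05 CPM after poly(dA:dT) and 111 ± 0.847 after poly(I:C). Of 27 oxidative phosphorylation genes 26 were lower (adjusted p = 9.76e-08), of 25 genes of G2 and M phase 20 were lower and 2 higher (adjusted p = 1.35e-06), and of 22 actin and contractile genes 17 were lower and 2 higher (adjusted p = 0.000415), with equal counts adjusted over the lists alone. For G2 and M phase 1 was higher without poly(dA:dT) replicate 1 or 2, without poly(I:C) replicate 1 or 3, with DESeq2 or without a filter. Kif20a, a mitotic kinesin gene, had a log2 fold change of -0.55 ± 0.03 (SE), and Flna, filamin A, one of -0.43 ± 0.02. The S phase list, with 15 higher, 5 lower and 5 not called, also adjusted over the list alone, passed camera (adjusted p = 0.0371, and adjusted p = 0.095 with an estimated correlation). Its call ended without poly(dA:dT) replicate 1 (adjusted p = 0.0619), poly(dA:dT) replicate 2 (0.0618) or poly(I:C) replicate 1 (0.0572).

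Mitochondrially encoded transcripts were higher after poly(I:C) than after poly(dA:dT) in 8 of 10 cases, with 2 not called, also adjusted over the list alone (camera, adjusted p = 4.92e-05, and adjusted p = 0.0606 with an estimated correlation), beside mitochondrial shares of 0.432% and 0.261%. Ribosomal protein genes were lower in 26 of 28 cases and higher in 2 (adjusted p = 1.36e-07, and adjusted p = 0.116 with an estimated correlation), with 1 higher without a filter. Extracellular matrix genes were lower in 15 of 27 cases and higher in 7 (adjusted p = 0.0127, and adjusted p = 0.168 with an estimated correlation). Glycolysis and hypoxia genes were lower in 15 of 22 cases and higher in 4 (adjusted p = 0.00391, and adjusted p = 0.05 with an estimated correlation). Counts of these 3 lists were equal when adjusted over the list alone. No marker list was called: macrophage (3 of 6 higher and 1 lower, adjusted p = 0.826), endothelial (2 of 6 higher, adjusted p = 0.486), epithelial (2 of 5 higher, adjusted p = 0.949), neural (0 of 6 changed, adjusted p = 0.656) and muscle (1 of 5 higher and 2 lower, adjusted p = 0.985). Adjusted over the list alone, 1 endothelial and 1 epithelial marker were higher. The epithelial list had a median log2 fold change of -0.10, a mean of 0.37 and a downward test direction, and fry gave the muscle list a downward direction where its median was 0.47. Marker counts moved by over 1.5 times here too, with 0 macrophage, endothelial, epithelial and muscle markers higher under the filter of 50 counts. With a library left out, 1 endothelial marker (poly(dA:dT) replicate 1 or 3, poly(I:C) replicate 1) or 1 epithelial marker (poly(dA:dT) replicate 2 or 3, poly(I:C) replicate 2 or 3) was higher, and up to 1 neural marker was higher and 1 lower. Muscle markers higher numbered 2 without poly(dA:dT) replicate 1 or poly(I:C) replicate 1, and without poly(I:C) replicate 2 there were 0 higher and 1 lower. Lower were 2 macrophage markers without poly(dA:dT) replicate 2 and 1 epithelial marker without poly(dA:dT) replicate 3. A filter of at least 50 counts in 3 libraries left 550 genes that differed at least 2-fold between the treatments.

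Most genes changed by poly(dA:dT) changed in the same direction after poly(I:C). Of the 544 genes at least 2-fold higher after poly(dA:dT), 514 were at least 2-fold higher after poly(I:C), 401 were called higher in poly(I:C) than in poly(dA:dT) and 27 lower. Of the 1858 genes at least 2-fold higher after poly(I:C), 728 were not called higher after poly(dA:dT). Called higher in both treatments were 3378 genes, where independent lists give 1501, and called lower in both were 3443, where independent lists give 1349. Simulated unchanged groups against shared simulated mock libraries gave a mean of 0 in 20 draws. With no change simulated, calls near 0 were bound to follow, so this is no measure for the overlap of real responses. In opposite directions 174 genes were called, 76 of them higher after poly(dA:dT) and lower after poly(I:C). The covariance of the log2 fold changes across genes was 0.534, beside a simulated mean of 0.023, and their correlation was 0.857, beside 0.463, across genes that are not independent replicates. The 3 mock libraries cannot be split into groups of 2, so part of the excess overlap may come from the shared controls. For the covariance, the simulated spread of shared controls gave at most 0.0256, which argues against that spread as its main source.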

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

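No result here rests on an alternative chosen after the data were seen; all were planned. In edgeR, 7490, 10787 and 8981 genes were called in poly(dA:dT) against mock, poly(I:C) against mock and poly(I:C) against poly(dA:dT). These counts stayed within 1.5 times under every alternative, with ranges of 6816 to 7177, 10387 to 10740 and 8442 to 8706 when a library was left out, and 6343, 10291 and 7943 calls by DESeq2. The counts of genes changed at least 2-fold, 553, 2006 and 1138, fell to 299, 1151 and 550 under the filter of 50 counts, which tests 11717 genes. They ranged over 538 to 571, 2032 to 2191 and 1156 to 1238 when a library was left out. The covariance of the treatments' fold changes, 0.534, was 0.896 without a filter and 0.382 under the filter of 50 counts, settings that add or remove genes of low counts, and 0.537 to 0.63 when a library was left out; the cause of the last shift was not tested. Camera called 15, 16 and 19 lists, and 15, 16 and 18 to 19 when a library was left out; an estimated correlation left 12, 13 and 13, and fry called 22, 23 and 20. Of 358 results for named genes none reversed under 5323 alternatives. Calls were lost in 73 of these, 43 with a library left out, and gained in 3. The losses with a library left out were Adgrb3, C1ql1, Ces1g, Dnm3os, Bik, Dcn and Cd68 (poly(dA:dT) against mock), Lyz2, Krt14, Stmn2, Tnnt2, Eng and mt-Nd3 (poly(I:C) against mock), and Ankrd37, Cdh1, Csf1r, Pecam1, Tnnc1 and Tnnt2 (between the treatments). With the replicate number as a block, edgeR called 7384, 10724 and 8905 genes, and among named genes only Bik (poly(dA:dT) against mock) and Cdh1 (between the treatments) lost their calls. Of the counts of list members, the block moved by over 1.5 times the sensors lower after poly(dA:dT) than in mock (1 to 0) and, between the treatments, the MHC class I genes lower (1 to 0), the cholesterol synthesis genes higher (1 to 0) and the epithelial markers higher (2 to 1). Deviations of same-numbered libraries correlated at -0.014 to 0.023 in 9 pairs, and 3 of 9 libraries correlated best with their own number. Of the counts of list members, 88 moved by over 1.5 times under other settings and 65 with a library left out. Depth limits genes of low counts, since 0 counts allow up to 0.107 CPM in the deepest library and 0.18 CPM in the shallowest.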

Other observations

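All tests in this part were chosen only after the result was seen, except those of receptor genes, of read-through and of the list counts in other splits. Transcripts of replication-dependent histones, a set chosen after its values were seen, rose after both treatments. Of 29 tested genes, 16 rose and 13 were not called after poly(dA:dT) (edgeR), with a median log2 fold change of 1.23, and 27 rose and 2 were not called after poly(I:C), with a median of 3.75. Their summed expression was 39.8 ± 1.39 CPM in mock, 111 ± 4.16 after poly(dA:dT) and 459 ± 1.04 after poly(I:C) (SD, n = 3). Hist1h1c, a linker histone gene, stood at 20.3, 56.6 and 200 CPM, and Hist1h2bc at 3.97, 14.9 and 51.9 CPM. Of 11 replacement histone genes, whose transcripts are polyadenylated, 5 rose and 6 fell after poly(I:C), with a median of -0.10. Near-identical histone copies can exchange reads, so single genes are uncertain.

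A few genes moved in opposite directions by at least 0.5 on the log2 scale after poly(dA:dT), and they too were named after their values were seen. Trp53inp1 had log2 fold changes of 0.92 after poly(dA:dT) and -0.79 after poly(I:C), Ddit4, a stress-induced inhibitor of mTORC1, 0.57 and -0.43, Mmp15 0.53 and -0.78, and Lpin1, a regulator of lipid metabolism, 0.60 and -0.36. Ndnf, a secreted protein gene, moved the other way, with -0.61 and 0.64. Among genes tested, 30.1% of 1045 long non-coding or unconfirmed genes and 23.2% of 314 pseudogenes rose at least 2-fold after poly(I:C), beside 11.4% of 12725 protein-coding genes. After poly(dA:dT) these shares were 8.61%, 7.32% and 3.36%.

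The first pattern weighed was that the poly(dA:dT) response was a smaller version of the poly(I:C) response. Carry-over of poly(I:C) RNA or reads would give each induced gene an equal share of its poly(I:C) rise, but 62.3% of 289 induced genes lay over 3 standard errors from the median share of 12%, and shares ran from 2.23% to 45.4% (5th to 95th percentile). It would also keep p53 targets at least as high after poly(I:C), but 13 of the 16 that rose after poly(dA:dT) were lower after poly(I:C). Both values argue against carry-over as the whole source, and a small share is left open. The difference between a DNA and an RNA mimic, which the design names, stays open as untested.

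The second pattern was that silent and non-coding genes were counted more after poly(I:C). Higher depth cannot account for it, since the poly(I:C) libraries were not deeper, with 16082772 to 22382837 counts against 19826550 to 29219797 in mock. Thinned to 16082772 counts per library, the poly(I:C) libraries detected 1749 more genes than mock. More genomic DNA or intergenic background is a candidate source for the receptor genes, whose sum rose 3.43-fold, and 4.63-fold without the 5 most counted. The 992 called genes under 1 CPM in mock that rose at least 2-fold rose by a median of 0.367 CPM per kb, 181 times the receptor genes' 0.00203, more than background as even as theirs adds; 100% rose by over 3 times it, but the filter and the 2-fold limit alone set that for 100% of them, so an uneven background is left open. Read-through past the 3' end of induced genes was argued against by medians of 2.00 past the 3' end and 2.95 before the 5' end, a difference of -0.95 (permutation p = 0.2), but both exceeded the 0.91 elsewhere, so a local rise on both sides is left open.

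The third pattern was the rise of replication-dependent histone transcripts, which mostly lack poly(A) tails. Weaker selection of polyadenylated RNA was weighed with other RNAs without tails, whose sum rose 1.6-fold (SE 0.0854) where the histone sum rose 11.5-fold. That sum was low, at 6.11 CPM in mock and 9.75 CPM after poly(I:C) over 1393 genes. Its members differed: Terc went from 6, 6 and 3 counts in mock to 37, 34 and 32 after poly(I:C), and Rn7sk from 24, 26 and 19 to 18, 29 and 17. The sum lay under 0.5 of the histone ratio, but so few counts with such unlike members cannot decide the explanation. The first bounds set for this test, at least 2 for the explanation and under 1.5 against it, left 1.6 undecided, and the comparison with 0.5 of the histone ratio was set after that value was seen. A larger share of cells in S phase as the whole source is argued against by the S phase list, whose median log2 fold change after poly(I:C) was 0.0835. Of its 25 genes 16 rose and 6 fell, and fry called the list upward (adjusted p = 2.43e-07), so a small part is left open. How far this list scales with histone transcripts was not tested. No other biological explanation was tested.

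Other splits of each pair of groups into 3 and 3 libraries were fitted with edgeR. For each comparison the 10 splits are too few for a share under 0.05. Genes changed numbered 7387, 10691 and 8994 in the real splits of poly(dA:dT) against mock, poly(I:C) against mock and poly(I:C) against poly(dA:dT), and genes changed at least 2-fold 399, 1879 and 1099. The highest of the other splits gave 0 in each case, so that 1 split, the real one, gave as many. Every other split held libraries of both groups on each side, so the difference between the groups entered the spread. Calls near 0 were bound to follow there, and they do not measure how many genes the spread between replicates alone would give. Camera called 15, 16 and 19 lists in the real splits and at most 16, 16 and 15 in the others, with 2, 3 and 1 splits giving as many. The other splits mixed the groups unevenly, so part of the difference between the groups stayed in the contrast. List calls could follow from that part, so these numbers do not measure how many lists chance alone would give.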
